A study of Zea mays with 12 samples.

How the data were processed

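Seedlings of the maize inbred lines B73 and Mo17, 14 days old and grown with 16 h of light at 28 °C and 8 h of dark at 25 °C, were profiled in 12 samples. Each line had 2 m6A-seq samples, 2 RNA-seq samples and 2 polysome profiling samples. In m6A-seq an antibody enriches RNA fragments that carry N6-methyladenosine, and in polysome profiling the RNA bound to polysomes is recovered and sequenced. Per the labels' protocols, libraries were made with the same kit for the 3 assays. Groups were taken from the labels. The labels do not state that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

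The submitters' processing notes name Trimmomatic 0.35, HISAT2 and MACS2, and the genome build B73 RefGen_v4. The build used for Mo17, the annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Mo17 peak coordinates were checked against the gene spans of both tables: 75.8% and 76.5% of the summits of the 2 Mo17 lists lay in exactly 1 Mo17 span, and 9.79% and 9.85% lay in spans of the B73 models. Mo17 coordinates are therefore given as the Mo17 files list them, with no build name.

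The peak lists were deposited by the authors as 1 list per sample, with the fold enrichment (a ratio), the −log10 p, the −log10 q and an integer score of each peak, and the offset of its summit. The control behind each enrichment is not given in the sources used here. These values are the authors' own and were used to describe, filter or rank peaks within a list. The expression tables were deposited by the authors as FPKM per gene (fragments scaled by gene length and by library size), 1 table per sample, with the gene's span and strand. How the FPKM were computed is not given in the sources used here. FPKM carry no depth, and whole reads were not recoverable, so the depth behind each value is unknown and no counting interval is given. The p-values behind the authors' −log10 values were not recomputed.

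B73 and Mo17 tables use different gene identifiers, and the files do not pair them. The B73 table holds 45577 features: 43788 gene models with Zm identifiers, 1635 features with ENSRNA identifiers (non-coding RNA genes predicted by Ensembl) and 154 microRNA genes. The Mo17 table holds 37843 gene models with Zm identifiers. A gene whose span differed between libraries was left out (1 in B73, 2 in Mo17). Of all identifiers, 153 microRNA genes of B73 matched a symbol in the reference table, and 0 identifiers of Mo17 did. The comparisons of Mo17 with B73 gene by gene were therefore not run, and the 28 gene lists fixed beforehand, which rest on gene descriptions, had 0 measured members. Each line was fitted alone on its 4 libraries, the fallback fixed for this case.

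Peaks of replicates were compared with bedtools 2.31.1, and an overlap of at least 1 bp counted as shared. A peak was assigned to a gene when its summit lay in the span of exactly 1 gene. A gene was called methylated when it had a peak in both replicates, and unmethylated when it had none in either. Genes with a peak in a single replicate, or with a summit that several gene spans share, were left out of that comparison. A gene was called expressed at an FPKM of at least 1 in both RNA libraries. Peaks could not be placed in exons or untranslated regions, since no annotation of either build was used here; positions are along the gene span, introns included.

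Polysome and total RNA libraries were compared with limma 3.58.1 (R 4.3.3, trend on) on log2(FPKM + 1), for genes with an FPKM of at least 1 in at least 2 of the 4 libraries, with 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 ratio of at least 1. Log2 ratios are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. They are relative to the other transcripts of a library, not absolute amounts. Sets of genes were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Differences between medians of gene groups are given as mean or pooled value ± SD over the 2 replicate numbers, with no p-value across genes. For ratios, this SD sets same-numbered polysome and RNA libraries together, though they may not be paired. Methylation calls from both m6A samples are held fixed in it, so it leaves out their spread. Tables were handled with pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. On data simulated from the B73 means and spreads, 100 genes were changed by a log2 ratio of 1.5 and 100 by 3. Of these, limma recovered 97% and 100%, with 23 false calls among the 19342 simulated genes. On data simulated from Mo17 in the same way, the shares were 98% and 100%, with 12 false calls among 20208 genes. Weighed against the changed genes recovered, rather than all genes, the false calls were not negligible, and there were more in B73. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 3, so recovery of weaker genes was not tried. Noise was simulated as independent between genes and libraries.

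Named genes followed a rule fixed before the data were examined. With no gene descriptions at hand, the 2 called genes with the largest log2 ratio each way were taken per line, if their libraries did not overlap and the higher group had a mean FPKM of at least 5. For peaks, the 2 genes per line with the highest smaller-of-2 fold enrichment were taken. MicroRNA genes and ENSRNA features were set apart only after the tables had been seen. Alternatives fixed beforehand were a pseudocount of 0.1, filters on FPKM, scaling by the median of log ratios, a replicate block, limma without trend, stricter peak thresholds, a larger overlap and leaving out each replicate. Others were added after the data were seen. Overlapping genes and paralogs are uncertain: 4.07% of tested B73 genes and 5.13% of tested Mo17 genes overlapped the span of another tested gene.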

Results

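m6A peaks, RNA levels and polysome-bound RNA levels were measured in seedlings of B73 and Mo17, 2 inbred lines of maize, with 2 replicates of each assay per line. The study set out to examine natural variation in m6A and its relation to translational status. The 4 m6A peak lists held 17399 and 16161 peaks in B73 and 16379 and 14846 in Mo17. The FPKM summed to 1147928 and 1157671 in the B73 RNA libraries and to 916681 and 934245 in the B73 polysome libraries. In Mo17 the sums were 665885 and 669811 for RNA and 800399 and 793281 for polysome RNA. Across genes, the log2 values of replicates had a Pearson correlation of 0.975 for RNA and 0.975 for polysome RNA in B73, and of 0.968 and 0.984 in Mo17; genes are not independent replicates. Ratios of the lines gene by gene were not computed, because the files do not pair their gene identifiers.

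m6A in both lines lay mainly at the 3′ ends of genes. In B73, 67.2% and 70.8% of the summits assigned to a gene fell in the last 10% of the gene span, where an even spread would also give 10%. In Mo17 the shares were 61.9% and 64.2%. The first 10% of the span held 2.05% and 1.90% of the B73 summits and 1.92% and 1.79% of the Mo17 summits. The median distance from the summit to the 3′ end was 232 and 215 bp in B73 and 325 and 312 bp in Mo17. Spans include introns and come from a different annotation in each line, so the difference between the lines was not tested.

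**Figure D1:**
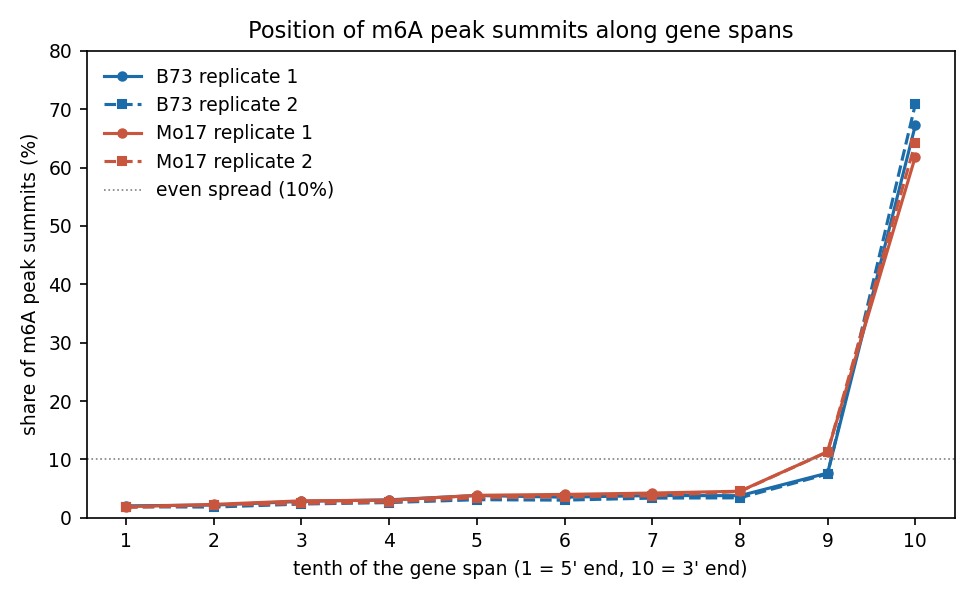
Share of m6A peak summits (y axis, percent) in each of 10 equal parts of the gene span from the 5′ to the 3′ end (x axis), for the 2 replicates of B73 (blue) and of Mo17 (red). The dotted line marks an even spread of 10%. All 4 lists rise to between 61.9% and 70.8% in the last part.

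Most peaks were found in both replicates. A peak of the other replicate overlapped 81.8% and 87.5% of the peaks in the 2 B73 lists (mean 84.6%). In the 2 Mo17 lists the shares were 81.5% and 88.4% (mean 84.9%). Both shares of a line come from the same pair of lists, so they give no spread between replicates. Shared peaks had higher enrichment than unshared ones in each list, with median folds of 7.44 against 5.66 and 7.84 against 5.65 in B73, and of 7.26 against 5.76 and 7.35 against 5.39 in Mo17. These folds are the authors' values, and the differences were not tested.

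Many expressed genes had a peak in both replicates, and how many depended on the peak threshold. In B73, 8769 of 17676 expressed features (49.6%) had a peak in both replicates, 7678 had none, and 1229 had a peak in a single replicate or one whose summit lay in several gene spans. In Mo17, 8190 of 19236 expressed genes (42.6%) were methylated and 9658 were not. With peaks of at least 5-fold enrichment the methylated genes numbered 6417 in B73 and 5802 in Mo17, and with a −log10 q of at least 10 they numbered 6084 and 5114. Among the B73 gene models alone the share was 50.9%. None of the 446 expressed ENSRNA features and none of the 12 expressed microRNA genes of B73 was assigned a peak in either replicate. Among tested B73 gene models in the shortest decile of span, only 1.85% were methylated. The absence was not matched for span, so it is not separated from an effect of short spans. The highest folds that held in both replicates lay at the ends of Zm00001d004153 (chromosome 2, 86910137 to 86914927, minus strand; folds 29.1 and 27.6) and Zm00001d013653 (chromosome 5, 16258269 to 16286212, plus strand; folds 27.5 and 29.5) in B73, coordinates in B73 RefGen_v4. In Mo17 they lay at the ends of Zm00014a_000209 (chromosome 9, 136212069 to 136226982, minus strand; folds 29.8 and 29.8) and Zm00014a_031947 (chromosome 9, 8942496 to 8951629, minus strand; folds 27.5 and 25.8). Their summits lay between 96.7% and 99.6% of the way along the gene. This ranking took all genes with a peak in both replicates, expressed or not. Zm00001d004153 had a total RNA FPKM of 0.773 ± 0.691 (SD, n = 2) and was not called expressed. The others had means of 2.70, 5.31 and 2.75, in the order given. The files do not pair these identifiers with names.

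Methylated genes had higher RNA levels than unmethylated genes in both lines. The difference of the median log2(FPKM + 1) was 0.33 ± 0.01 in B73 (SD, n = 2) and 0.59 ± 0.04 in Mo17 (SD, n = 2), larger than the spread between replicates. With peaks of at least 5-fold enrichment alone the difference turned in B73, to −0.21 ± 0.01 (SD, n = 2), and kept its direction in Mo17, at 0.065 ± 0.044 (SD, n = 2). In that setting genes with weaker peaks alone joined the unmethylated group, which grew from 8730 to 10237 genes in B73 and from 10418 to 11914 in Mo17. Among methylated gene models of B73, the median log2 RNA level was 3.70 in the tercile of lowest fold and 2.16 in the tercile of highest fold, and in Mo17 it was 4.42 and 2.96. Peak calls depend on RNA level, so a weak transcript can lack a peak for want of signal. These comparisons do not separate that from a difference in methylation.

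Transcripts differed widely in how far they were represented in polysomes. In B73, 3220 of 19342 tested genes were higher in polysome RNA than in total RNA and 1036 were lower, with a median log2 ratio of 0.29. In Mo17, 1024 of 20208 were higher and 3351 lower, with a median of −0.36. This split follows the scaling of the libraries. After scaling by the median of log ratios, which brings the median to 0.07 in B73 and 0.02 in Mo17, the counts were 1751 higher and 1464 lower in B73, and 2556 higher and 1276 lower in Mo17. After scaling to an equal sum over Zm gene models, an alternative added after the data were seen, the B73 split turned, to 675 higher and 2491 lower with a median of −0.19, and Mo17 had 494 higher and 5229 lower with a median of −0.56. Without RNA replicate 1 or RNA replicate 2, the count of higher genes in B73 was 1961 or 2001.

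Among the extremes in B73, Zm00001d045578 (chromosome 9, 27179112 to 27180859) rose from an FPKM of 0.780 ± 0.303 in total RNA to 93.9 ± 19.1 in polysome RNA (SD, n = 2), a log2 ratio of 5.73 ± 0.23 (SE, limma adjusted p = 2.57e-05). Zm00001d027021 (chromosome 4, 235760167 to 235761769) was listed at 0 and 0.00221 in total RNA and at 26.7 and 27.0 in polysome RNA. Zm00001d028301 (chromosome 1, 29685314 to 29685387) fell from 937.1 ± 97.6 to 3.90 ± 0.334 (SD, n = 2), a log2 ratio of −7.58 ± 0.16 (SE, limma adjusted p = 6.12e-06). ENSRNA049463813 (chromosome 5, 3433111 to 3433271) fell from 462.1 ± 40.9 to 1.61 ± 1.13 (SD, n = 2). In Mo17, Zm00014a_014255 and Zm00014a_005275 were listed at 0 in both RNA libraries. Their polysome FPKM were 17.4 and 17.5 for the former and 12.8 and 11.99 for the latter. Zm00014a_014255 was nonetheless called methylated, with a peak in both m6A replicates, so its 0 in total RNA need not mean that its RNA was absent. Zm00014a_005275 was unmethylated. Zm00014a_038392 fell from 63.3 ± 4.31 to 0.747 ± 0.467 (SD, n = 2), and Zm00014a_022197 from 1420 ± 21.5 to 69.0 ± 13.02 (SD, n = 2). The files give no names for these genes, and a value of 0 in a table without counts can be a failed estimate.

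ENSRNA features of B73, which are predicted non-coding RNA genes, were lower in polysome RNA than in total RNA as a group. Of 452 tested ENSRNA features, 365 were lower in polysome RNA and 11 were higher, with a median log2 ratio of −2.36 against 0.31 for the Zm gene models. These features held 60.5% and 62.1% of the FPKM in the RNA libraries and 26.5% and 25.8% in the polysome libraries. The camera test gave p = 1.66e-80 at the preset correlation and p = 0.00167 with an estimated correlation (6.62e-80 and 0.00668 after Benjamini-Hochberg adjustment over the 4 set tests of the series). With an equal sum over Zm gene models the median of the set was −2.72. The set was chosen after the tables had been seen. The type of RNA of each feature is not given in the sources used here. FPKM are shares of a library, so the composition of the libraries and absolute loss from polysomes cannot be told apart.

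Of 12 measured microRNA genes, whose transcripts are precursors of small regulatory RNAs, 4 were lower in polysome RNA and 0 were higher. The count depends on the scaling: median of log ratios scaling gave 6 lower and an equal sum over Zm gene models 7 lower, with 0 higher in each. MIR408b, which belongs to a copper-responsive family, fell from an FPKM of 33.3 ± 10.7 to 6.76 ± 0.799 (SD, n = 2), a log2 ratio of −2.11 ± 0.25 (SE, limma adjusted p = 0.00162). MIR398b, of another copper-responsive family, fell from 33.8 ± 6.65 to 11.2 ± 3.65 (SD, n = 2; log2 ratio −1.53, limma adjusted p = 0.00519, and 0.0628 without RNA replicate 1). MIR156e, of the family that marks the juvenile phase, and MIR393c, of a family that targets auxin receptors, fell, with log2 ratios of −1.54 and −1.48 (limma adjusted p = 0.00418 and 0.00519). Both calls rest on levels near the FPKM filter of 1. MIR156e went from 2.94 ± 0.997 to 0.333 ± 0.128 and MIR393c from 2.07 ± 0.863 to 0.0819 ± 0.116 (SD, n = 2). MIR399e and MIR399j, of the phosphate starvation family, had log2 ratios of 1.08 and 0.50 that did not pass the test (limma adjusted p = 0.150 and 0.279). That of MIR399e rested on RNA libraries that disagreed, at FPKM of 8.56 and 1.93: it passed without RNA replicate 1 (log2 ratio 1.93, limma adjusted p = 0.0349) and fell to 0.23 without RNA replicate 2 (limma adjusted p = 0.686). It also passed with a replicate block (limma adjusted p = 0.0391) and with a crossed block (0.0163), each of which gave 1 higher and 5 lower microRNA genes. The median of the 12 was −0.88. The camera test gave p = 1.91e-04 at the preset correlation and p = 0.144 with an estimated correlation, 3.82e-04 and 0.289 after adjustment. The fry test of the 12 gave a p of 0.0614, 0.0676 after adjustment. The spans of MIR398b, MIR156e and MIR393c overlap an ENSRNA feature on the same strand, so reads of the pairs cannot be told apart. The feature at MIR398b fell as well (log2 ratio −1.13, limma adjusted p = 0.00783), but the one at MIR156e was not called (log2 ratio −0.49, limma adjusted p = 0.493), and the one at MIR393c was under the FPKM filter. The span of MIR408b overlaps no other feature.

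**Figure D2:**
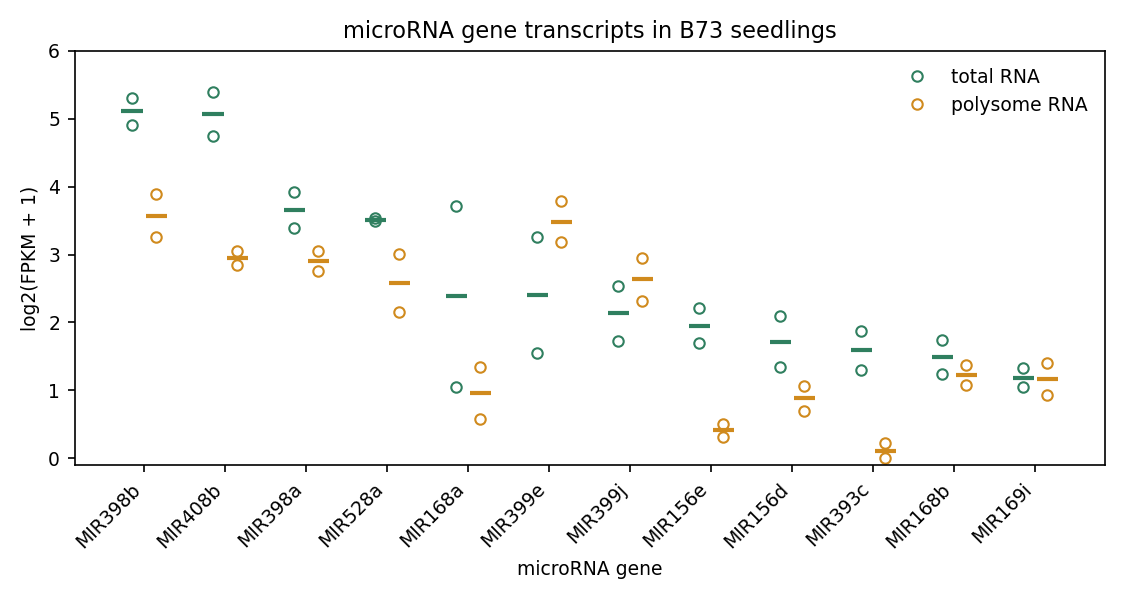
log2(FPKM + 1) (y axis) of the 12 measured microRNA genes of B73 (x axis, by falling mean in total RNA) in total RNA (green) and polysome RNA (orange). Circles are the 2 replicates and bars their mean. MIR408b lies at a mean FPKM of 33.3 in total RNA and 6.76 in polysome RNA.

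Methylated and unmethylated genes of the same line differed little in polysome to total RNA ratio when all tested genes were compared. The median log2 ratio was 0.34 in methylated and 0.25 in unmethylated genes of B73, a difference of 0.09 ± 0.06 (SD, n = 2). In Mo17 the medians were −0.32 and −0.39, a difference of 0.07 ± 0.12 (SD, n = 2), within the spread between replicate numbers. The camera test at the preset correlation gave p = 0.0507 in B73 and p = 0.473 in Mo17, 0.0676 and 0.473 after adjustment. With an estimated correlation the values were p = 0.686 and p = 0.781. The Mo17 set lies below 0 itself (fry p of 0.0194, 0.0389 after adjustment), but this direction depends on the library scaling. With median of log ratios scaling, which brings the median of all Mo17 genes to 0.02, the set had a median of 0.079, with 1263 genes higher and 380 lower. With an equal sum over Zm gene models it was −0.54, with 259 higher and 2072 lower. With the most abundant 1% left out of that sum it was −0.30, with 574 higher and 1169 lower. All ENSRNA features and microRNA genes that were tested are outside the methylated set of B73. With Zm gene models alone the B73 difference was 0.045 (camera p of 0.251), and with peaks of at least 5-fold enrichment 0.027 (camera p of 0.377). In B73 the test at the preset correlation passed 0.05, before adjustment, in 6 of 18 settings: with a replicate block (p = 0.0297, but p = 0.0561 with a crossed block), without m6A replicate 1 (p = 0.0498), without RNA replicate 2 (p = 0.0353), without polysome replicate 2 (p = 0.0268), at an FPKM of at least 5 (p = 0.00758) and with no filter on FPKM (p = 0.00435). The setting without trend repeated the main camera test, so it adds nothing to this count. With no filter the Mo17 difference was −0.06. Within 10 bins of RNA level the differences were 0.10 ± 0.05 and 0.12 ± 0.13 (SD, n = 2).

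The location of the peaks and their enrichment went with small differences in ratio. Methylated B73 gene models with peaks in the last 20% of the span alone had a median of 0.36 (7360 genes), those with peaks in the middle 60% alone a median of 0.43 (441 genes), and those with peaks in several parts a median of 0.17 (1376 genes). In Mo17 the values were −0.31 (6463 genes), −0.25 (689 genes) and −0.44 (1143 genes). The median fell from 0.42 in the tercile of lowest fold to 0.27 in that of highest fold in B73, and from −0.24 to −0.36 in Mo17. These groups also differed in RNA level and span, and the differences were not tested.

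Gene span separated methylated from unmethylated genes. The share of methylated genes rose from 1.85% in the shortest decile of B73 gene models to 88.6% in the longest, and from 0.99% to 80.8% in Mo17. In the third decile of span, methylated genes of B73 had a median log2 ratio of 0.98 (342 genes) against 0.24 in unmethylated genes, and methylated genes of Mo17 had 0.62 (210 genes) against −0.39. In the longest decile the medians were −0.07 and −0.13 in B73 and −0.69 and −0.76 in Mo17. The split by span was chosen after the data had been seen and was not matched for RNA level.

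**Figure D3:**
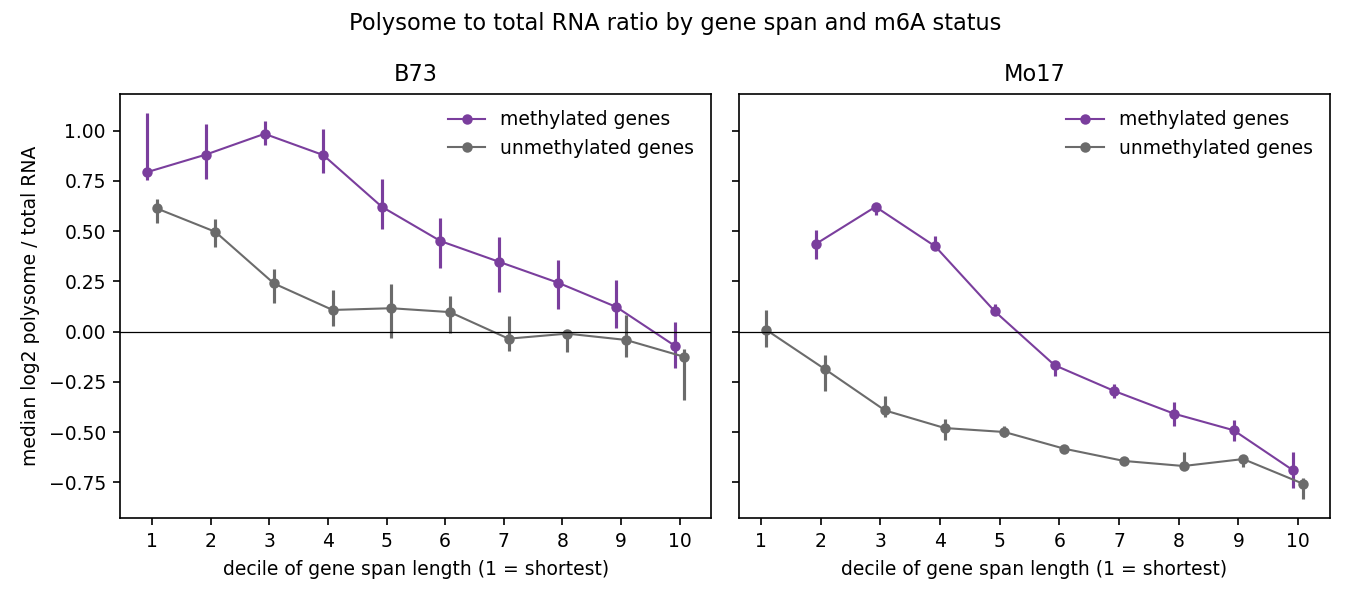
Median log2 polysome to total RNA ratio (y axis) of methylated (purple) and unmethylated (grey) Zm gene models by decile of gene span length (x axis, from the shortest), in B73 (left) and Mo17 (right). Vertical lines join the values of the 2 replicate numbers, and points of fewer than 30 genes are not drawn. In B73 the curves are furthest apart in the fourth decile (0.88 against 0.11), closer in the shortest (0.79 against 0.61) and closest in the longest.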

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

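All tests in this part were chosen after the results they bear on had been seen.

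The median log2 polysome to total RNA ratio over all genes was 0.29 in B73 and −0.36 in Mo17. It stands out because the values of both replicate numbers were above 0 in B73 (0.38 and 0.18) and below 0 in Mo17 (−0.36 and −0.36); the difference was not tested. Scaling the libraries to an equal sum over Zm gene models moved the median to −0.19 in B73 and −0.56 in Mo17, but this decides nothing about the ENSRNA features, which fill more of the B73 total RNA than of the B73 polysome FPKM: the sums, known beforehand, set how far the median moves, and Mo17, whose table lists no ENSRNA features, moved too. The most abundant 1% of genes were argued against as the whole cause of the Mo17 value: with an equal sum over the other genes the Mo17 median was still −0.34. Compared with the equal sum over all Zm gene models, leaving out this 1% raised the Mo17 median from −0.56 to −0.34. It raised that of B73 only from −0.19 to −0.17. Under equal sums, part of the Mo17 value thus went with these genes. The ENSRNA features and a difference between the lines stay open; the latter was not tested.

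Summits outside all gene spans made up 14.2% of the B73 peaks and 22.6% of the Mo17 peaks (means of 2 lists). The comparisons of genes above do not use these peaks, while the overlap of replicates does. Gene models of Mo17 that end up to 1000 bp short of their transcripts were argued against as the main cause. Of the excess of Mo17, 71.7% remained after peaks up to 1000 bp past a 3′ end were counted as genic. Models that end further short were not examined and stay open. Peaks more than 5000 bp from any gene span made up 40.5% of the excess, between the bounds set for and against loci without a gene model, so these may account for part of it. A difference between the lines stays open and was not tested.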

How the results depend on the processing

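Alternatives were fixed before the data were examined, except those on patterns found later and those named next. Equal sums, Zm gene models alone, the crossed block, joint bins, estimated correlations, and for the methylated set no filter, −log10 q, trend and median scaling, were added after results were seen. Causes of a move were not tested unless stated. Gene-by-gene comparisons of the lines, the gene lists and their alternatives were not run: identifiers are not paired. Fitting only the compared groups was not run: lines were fitted alone. Depth is unknown, and with 2 replicates per group 1 library can move a count. A lone library left in an arm was assumed to vary like the others.

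Peak overlap was 75.3% (B73) and 74.95% (Mo17) when a share of 0.5 of both peaks had to overlap, and 77.8% and 77.1% at 5-fold enrichment. Methylated genes numbered 4574 in B73 at an FPKM of at least 5, with fewer genes eligible, and 5114 in Mo17 at a −log10 q of at least 10, with fewer peaks. Median scaling gave 1751 higher genes in B73, and 2556 higher and 1276 lower in Mo17. Equal sums over Zm gene models gave 675 higher and 2491 lower in B73, and 494 higher and 5229 lower in Mo17. Zm gene models alone gave 668 lower in B73, since ENSRNA features were left out. Leaving out 1 library gave 1961 to 3947 higher and 797 to 1107 lower genes in B73, and 916 to 1307 higher and 2993 to 3748 lower in Mo17.

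Deviations of same-numbered RNA and polysome libraries had a correlation of −0.135 in B73 and −0.035 in Mo17, so the numbers gave no sign of pairing these libraries. Independent library noise would also give weak correlations, so pairing is not excluded. Pairing with the m6A lists was not examined. A replicate block gave 3349 higher and 1057 lower genes in B73, and 1052 and 3375 in Mo17. Crossed numbers gave 3333 and 1056 in B73. For the methylated set in B73 the block gave a camera p of 0.0297 and crossed numbers 0.0561, at the same difference, 0.088.

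The RNA level difference of methylated genes was 0.39 (B73) and 0.65 (Mo17) with a pseudocount of 0.1, and −0.21 and 0.065 at 5-fold enrichment. Leaving out 1 library gave 0.30 to 0.34 in B73 and 0.54 to 0.61 in Mo17. Their ratio difference in B73 was 0.13 at an FPKM of at least 5 and 0.22 with no filter, both past the threshold at the preset correlation (p = 0.686 for the main set at the estimated one), and −0.061 in Mo17 with no filter. Leaving out 1 library gave 0.066 to 0.13 in B73 and 0.0069 to 0.13 in Mo17. Joint bins of RNA level and span gave 0.37 and 0.43. Over 18 settings at the preset correlation, camera passed 0.05 in 6 for B73 (p from 0.00435 to 0.377), and in 0 of 16 for Mo17 (p from 0.153 to 0.962).

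The median ratio of B73 turned to −0.19 with equal sums over Zm gene models and to −0.17 when the most abundant 1% were left out of the sum. MIR169i, at −0.023, was 0.12 without RNA replicate 1 and 0.22 without polysome replicate 1, and from −0.26 to 0.22 when 1 library was left out. Of the other values for single genes, sets and trends, 278 stayed on their side of the threshold or within their spread, 32 moved, 15 lost and 12 gained the threshold.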

Other observations

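All tests in this part were chosen after the data had been seen, except the difference within bins of RNA level and that with crossed replicate numbers over all genes.

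Short genes and abundant transcripts had the highest median polysome to total RNA ratios in both lines. The shortest decile of span was mixed, with 492 genes higher and 220 lower in B73, and 154 higher and 265 lower in Mo17. Across Zm gene models, the ratio had a Spearman correlation with span length of −0.22 in B73 and −0.22 in Mo17; genes are not independent replicates. With the mean level over the 4 libraries, which contains both parts of the ratio, the correlation was 0.35 in B73 and 0.25 in Mo17. The median log2 ratio went from 0.01 in the decile of lowest level to 0.95 in that of highest level in B73, and from −0.46 to 0.35 in Mo17.

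Over all tested genes, no test settled why methylated genes had a slightly higher median ratio. Within 10 bins of RNA level the difference was 0.10 ± 0.05 in B73 and 0.12 ± 0.13 in Mo17 (SD, n = 2), and within 10 bins of the mean level over all 4 libraries it was 0.038 and 0.058. The bound against RNA level, 0.05, was set only after results had been seen. The B73 value within bins of RNA level passed it by slightly more than its spread, and the Mo17 value did not. The direction also turned with level: in the decile of Zm gene models with the lowest mean level the medians of methylated and unmethylated genes were −0.04 and 0.03 in B73 and −0.49 and −0.45 in Mo17, and in that with the highest 1.08 and 0.83, and 0.47 and 0.27. With peaks of one replicate number set against the ratio of the other it was 0.086 and 0.065. With Zm gene models alone it was 0.045 in B73. These lay within their spread of the bounds set against shared noise and non-coding features. Both stay open as causes of this small difference, and so does RNA level taken alone, since within bins of RNA level the difference was 0.047 with Zm gene models alone in B73. RNA level and span together were argued against as its cause: holding both enlarged it, to 0.37 and 0.43, where it would have been 0.02 or less. As methylated genes were longer and long genes had lower ratios, holding span can enlarge the difference by itself, so these bins do not decide on RNA level alone. That result prompted the comparison that follows.

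Among genes of like RNA level and span, methylated genes had a higher ratio than unmethylated genes, by 0.37 ± 0.04 in B73 and 0.43 ± 0.06 in Mo17 (SD, n = 2), with the same sign in 81 of 87 and 84 of 87 bins. Crossed replicate numbers gave 0.34 and 0.40, but noise shared by the peak call and the ratio stays open. The control of the peak calls is unknown, and so is whether replicate numbers pair the libraries. Weakly expressed gene models were argued against by 0.46 and 0.49 at an FPKM of at least 5. ENSRNA features and microRNA genes were argued against by 0.38 in B73 with Zm gene models alone. Non-coding transcripts among the Zm gene models were not identified, so these stay open. Bins of RNA level share the denominator of the ratio; bins of the mean level over all 4 libraries lowered the difference to 0.30 and 0.33, which leaves most of it.

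Whether m6A goes with polysome loading once RNA level and span are held stays open. cameraPR on statistics centred within bins gave p = 2.3e-05 in B73 and p = 1.82e-05 in Mo17 at a correlation of 0.01 (2.3e-05 in each after Benjamini-Hochberg adjustment). At a correlation of 0.05 the p-values were 0.0557 and 0.0528 (0.0557 in each after adjustment), and the correlation estimated for the set of methylated genes was 0.178 in B73 and 0.0522 in Mo17. The test therefore does not settle it. Properties that were not matched, such as coding length, transcript class or the quality of the gene model, may also differ between the groups, and no biological explanation was tested.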
